A study of Arabidopsis thaliana with 14 samples.

How the data were processed

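The values came from the deposited series matrix, and they were read as log2 values. The labels do not state the scale. It was inferred from the range, since the highest deposited value lay under 16. The method of normalization is not given in the sources used here, and no further normalization was applied before the tests. The lowest value was 0 and values carried 2 decimals. Of 21253 value rows, 58 Affymetrix control rows were left out and 21195 loci were tested. Every column of the file was used. A total of 21097 loci were matched by locus identifier to the RefSeq gene table of assembly TAIR10.1, and 98 were not. Symbols were taken from that table, and a locus identifier stands where the table holds no symbol. Detection calls were not used here.

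Per the labels' protocols, whole inflorescences of primary and secondary branches were collected up to about floral stage 10. They were pooled from 3 to 10 plants and frozen. RNA was extracted with a Sigma kit and labelled with the GeneAtlas 3' IVT Express kit. Meristems were cut by laser from 10 µm sections of at least 20 plants. Their RNA was extracted with PicoPure and amplified with RiboAmp Plus before labelling, per the same protocols. Plants grew in 16 h light at 20 °C and 8 h dark at 16 °C with 60% humidity. The protocol names removal of all but 3 to 4 fruits, whereas the series text names removal of all fruits. The time course arrays carry a label of the ms1-1 co-segregant wild type, whereas the protocol names Ler. Sample titles hold a code that begins with r or g, and its meaning is not given in the sources used here. Group names and arrays were taken from the labels as they stand. MS1 has no value row here, so the genotype label of the sterile arrays could not be checked by that gene.

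The 10 inflorescence arrays were fitted together with 1 mean per group (6 groups). Moderated t tests from limma 3.58.1 under R 4.3.3 used lmFit, contrasts.fit and eBayes with default settings. The 8 comparisons were each adjusted over all tested loci by Benjamini-Hochberg, and a locus was called at an adjusted p under 0.05, two-sided. The r or g code was not a term of this fit. A gene is said to have risen or fallen only where it was called. Values after ± are standard errors from the same fit. Adjusted p-values of genes are from limma throughout. The fertile growing and sterile growing groups had 1 array each, and their arrays were assumed to vary like the others.

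Named genes were the 10 called genes with the largest rise and the 10 with the largest fall per comparison, provided that the arrays of the groups did not overlap and that the locus was in the gene table. This gave 160 gene and comparison pairs over 83 different genes. For each list, the up to 4 members with the lowest p-value could be named as well. A gene named outside these rules is said to have been chosen after the values were seen. For meristems, the 10 largest differences in each direction were taken among genes whose higher value lay above the median of its array.

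Gene lists were written from general knowledge as symbol and locus pairs before the values were opened. The 22 lists were DNA replication and S phase, mitosis and cytokinesis, core histones, ribosomal and nucleolar proteins, bud dormancy and low-sugar response, abscisic acid response, auxin response, cytokinin response, jasmonate synthesis and response, senescence and chlorophyll breakdown, shoot meristem regulators, floral identity and MADS-box factors, anther and tapetum markers, meiosis markers, photosynthesis, vascular markers, epidermis markers, heat shock, wounding and oxidative burst, antioxidant enzymes, morning clock genes and evening clock genes. Members were matched by locus, and a member was used if its symbol was among the table's names for that locus. Of 337 members, 281 were used, 41 had no value row and 15 had another name in the table. Another 8 lists with 80 members, of which 67 were used, were chosen after the main results had been seen. They were flavonoid synthesis, aliphatic glucosinolate synthesis, indolic glucosinolate synthesis, late pollen markers, dawn-phased genes, evening-phased genes, copper deficiency genes and copper proteins.

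Shifts of whole lists were tested by camera from limma with a preset correlation between genes of 0.01, adjusted over the 176 tests of 22 lists and 8 comparisons. Camera compares the moderated t statistics of a list with those of all other genes. The medians printed beside its p-values describe the list and were not themselves tested. Of these, 80 passed an adjusted p under 0.05. With a correlation estimated from the data, 0 passed, and 14 had an unadjusted p under 0.05. With fry from limma, which tests a list against no change and not against other genes, 46 passed. Counts marked as adjusted over the list alone used Benjamini-Hochberg over the members of that list.

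The 4 meristem arrays had 1 array per group, so no test was made. Differences of at least 4-fold were counted, and each list's median was ranked among 10000 random lists of the same size drawn from 20 bins of mean expression. Simulations of unchanged groups with the observed spread were made 20 times. In the self-test, 200 of 21195 loci were changed by known folds, in 1 simulated set per comparison with a like spread in every group. Most comparisons of the data held far more calls. Their groups also had unlike spreads (median standard deviation 0.24 in arrested, 0.085 at 6 h). The shares below therefore do not carry over to the data as they stand. At 2-fold, 5% of changed loci were called for sterile growing minus arrested and 36.2% for 6 h minus arrested, the lowest and highest shares. At 4-fold, 71.9% were called for sterile minus fertile, the lowest share. Unchanged loci made up from 3.3% (growing minus arrested) to 11% (24 h minus arrested) of the calls. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.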

Results

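The series held 14 arrays of Arabidopsis thaliana in the Landsberg erecta background, 10 of whole inflorescences and 4 of laser-dissected shoot meristems. Inflorescences were labelled as arrested (2 arrays), fertile and growing (1 array), male sterile ms1-1 and growing (1 array), or taken 6 h, 24 h and 48 h after fruit removal (2 arrays each). Meristems were labelled as arrested, fertile growing, sterile growing, or from plants whose fruits had been removed 48 h before, with 1 array each. Whether replicate arrays came from independent plants is not stated in the labels, so p-values measure the spread between these samples of pooled plants. That spread was shared over the replicate pairs, and the lone growing arrays added nothing to it. The median standard deviation was 0.24 in arrested, 0.085 at 6 h and 0.163 at 24 h and 48 h. For comparisons with arrested, p-values and standard errors rested in part on these tighter pairs and can be too small.

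Array medians ranged from 7.27 to 7.45 in inflorescences and from 7.43 to 7.49 in meristems, all log2. The sterile growing array had the highest inflorescence median, and over all genes the median difference from arrested was 0.2. Replicates at 6 h, 24 h and 48 h correlated at 0.991, 0.982 and 0.975. The arrested replicates correlated at 0.947, and 1 of them carried an r code and the other a g code. Their values differed in genes of low sugar and dormancy: ASN1, an asparagine synthetase induced in the dark, read 7.03 and 11.85, and SEN1 read 7.18 and 13.37 (genes chosen after the values were seen). Both growing arrays were r-coded and every fruit removal array was g-coded, so an effect of the code could be estimated only from the arrested pair, where it goes together with the difference between replicates.

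Genes of dividing cells and of the tapetum were higher in growing inflorescences, and most senescence genes and parts of the dormancy and abscisic acid lists were lower. Among 19 genes of mitosis and cytokinesis, all rose in growing over arrested inflorescences (19 adjusted over the list alone), among them the cyclin CYCB1;1 (log2 difference 2.87 ± 0.27, adjusted p = 0.00038) and the spindle protein TPX2 (3.12 ± 0.32). In the replication list 14 of 17 genes rose and 3 were not called (15 rose adjusted over the list alone), including the sliding clamp PCNA1 (3.03 ± 0.22) and the helicase subunit MCM7 (3.18 ± 0.29). Of 13 core histones, 11 rose and 2 were not called, with HTA6 at 3.16 and HTB2 at 2.43 (11 rose and 1 fell adjusted over the list alone). The largest rise in this comparison was that of CYP704B1, a fatty acid hydroxylase of the pollen wall precursor (8.03 ± 0.42, adjusted p = 7.3e-05). With it rose 14 of 16 anther and tapetum markers, while 2 were not called (15 rose adjusted over the list alone), and ACOS5, CYP703A2 and DRL1 of the same sporopollenin pathway rose by 4.08, 5.56 and 3.95.

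Senescence genes moved the other way: 11 of 17 fell and 6 were not called (12 fell adjusted over the list alone). SAG21 (-4.75 ± 0.24), the cysteine protease SAG12 (-3.52 ± 0.3), the transcription factor NAP (-3.53 ± 0.34) and the chlorophyll breakdown gene NYE1 (-1.88 ± 0.2) were among them. Of 22 dormancy and low-sugar genes 7 fell and 15 were not called (9 fell adjusted over the list alone), and these included the bud dormancy homeobox genes HB53 (-2.51 ± 0.2), HB21 (-2.84 ± 0.24) and HB40 (-2.14 ± 0.27). The mean of this list was 8.63 and 11.11 in the arrested arrays, 7.46 in the sterile and 9.2 in the fertile growing array, so the fertile array lay above 1 arrested array. In the abscisic acid list 7 genes fell, 1 rose and 14 were not called (7 fell and 1 rose adjusted over the list alone), with HB-7 at -2.99 ± 0.39, RD22 at -1.38 and the phosphatase ABI1 at -0.95, and the list mean of the fertile growing array (8.59) lay above that of the g-coded arrested array (8.46). Cytokinin response fell as well, since 7 of 12 genes were lower and 5 not called (7 fell adjusted over the list alone), led by the response regulators ARR4 (-2.04 ± 0.22) and ARR8 (-1.74 ± 0.28). All 4 morning clock genes fell, among them CCA1 (-4.41 ± 0.35) and LHY (-2.52 ± 0.3). Among the named genes, the male germline F-box gene DAF1 (-6.75 ± 0.4), the serine carboxypeptidase-like gene scpl38 (-6.16), the carbonic anhydrase ACA3 (-6.06) and the iron superoxide dismutase FSD1 (-5.94 ± 0.42) were among the largest falls.

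In most other lists fewer genes were called. Of 17 shoot meristem regulators 1 rose, 3 fell and 13 were not called (1 rose and 3 fell adjusted over the list alone): the stem cell gene WUS rose by 2.46, and TFL1, CLV1 and BLH9 stood at -1.69, -1.12 and -0.78. Floral identity genes split into 5 that rose, 2 that fell and 9 not called (5 and 3 adjusted over the list alone), with AG at 1.6 and SHP1 at 1.67 against FUL at -1.69. Among meiosis markers 2 rose, 1 fell and 4 were not called (4 rose and 1 fell adjusted over the list alone), the recombinase DMC1 at 2.54 and MER3 at 1.97 against SYN1 at -0.73. Photosynthesis genes fell in 4 of 11 cases, with 7 not called (4 fell adjusted over the list alone), PSBO1 at -0.75, and all 11 had negative differences. Ribosomal and nucleolar genes held 1 riser of 12, RPL5A at 0.89, and 11 had positive differences. Auxin response held 2 risers and 1 faller of 11 (4 and 2 adjusted over the list alone), with GH3.5 at -2.2 and IAA19 at 1.65. JAZ12 (-1.07) alone was called among 15 jasmonate genes. In the vascular list 2 of 8 fell, the phloem genes SUC2 (-2.65) and APL (-1.05), and in the epidermis list 2 rose and 2 fell of 7, with PDF1 at 1.62 and KCS6 at -1.42. HSFA2 (1.64) alone was called of 9 heat shock genes, and WRKY33 and ZAT10 (both -2) of 12 wounding genes. In the antioxidant list 2 rose and 3 fell of 8, the copper-zinc superoxide dismutases CSD2 (3.26) and CSD1 (2) against FSD1 and the catalase CAT2 (-2.87). Evening clock genes held 3 risers of 6, ELF4 (1.65), GRP7 (1) and TOC1 (1.01). Adjusted over the list alone, the ribosomal, epidermis, heat shock, wounding, antioxidant and clock lists kept these counts, the vascular list held 2 rises and 2 falls, and JAZ12 was not called. With the r or g code as a block GRP7, TOC1, JAZ12, PSBO1 and ZAT10 were not called, and the evening list mean was 9.74 and 8.7 in the r-coded and g-coded arrested arrays against 9.72 in the sterile and 10.14 in the fertile growing one.

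Across all tested loci 5483 were called between growing and arrested inflorescences, 2957 higher and 2526 lower, and 1701 and 1784 of these differed at least by a factor of 2. By camera these lists differed from other genes: tapetum (median 3.72, adjusted p = 3.5e-12, adjusted p = 0.3 with an estimated correlation), mitosis (2.25, adjusted p = 4.8e-11, adjusted p = 0.55 with an estimated correlation) and replication (2.04, adjusted p = 2.8e-09, adjusted p = 0.55 with an estimated correlation). The same held for histones (1.36, adjusted p = 2.1e-06, adjusted p = 0.55 with an estimated correlation), senescence (-1.88, adjusted p = 1.2e-06, adjusted p = 0.55 with an estimated correlation) and cytokinin response (-1.03, adjusted p = 0.00019, adjusted p = 0.55 with an estimated correlation). Morning clock genes (-2.63, adjusted p = 0.00058, adjusted p = 0.55 with an estimated correlation), photosynthesis (-0.68, adjusted p = 0.0027, adjusted p = 0.67 with an estimated correlation) and abscisic acid response (-0.57, adjusted p = 0.009, adjusted p = 0.57 with an estimated correlation) also shifted. So did dormancy (-1.48, adjusted p = 0.00015, adjusted p = 0.72 with an estimated correlation) and ribosomal genes (0.47, adjusted p = 0.028, adjusted p = 0.69 with an estimated correlation). The meristem regulators had a median of 0.04 and a mean of 0.07 while the test pointed down (adjusted p = 0.72), and the epidermis list had a median of 0.24 and a mean of -0.01 while the test pointed up (adjusted p = 0.97). With the r or g code as a block the dormancy shift was not called (adjusted p = 0.27). The list medians of each comparison are drawn in the colour map.

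**Figure D1:**
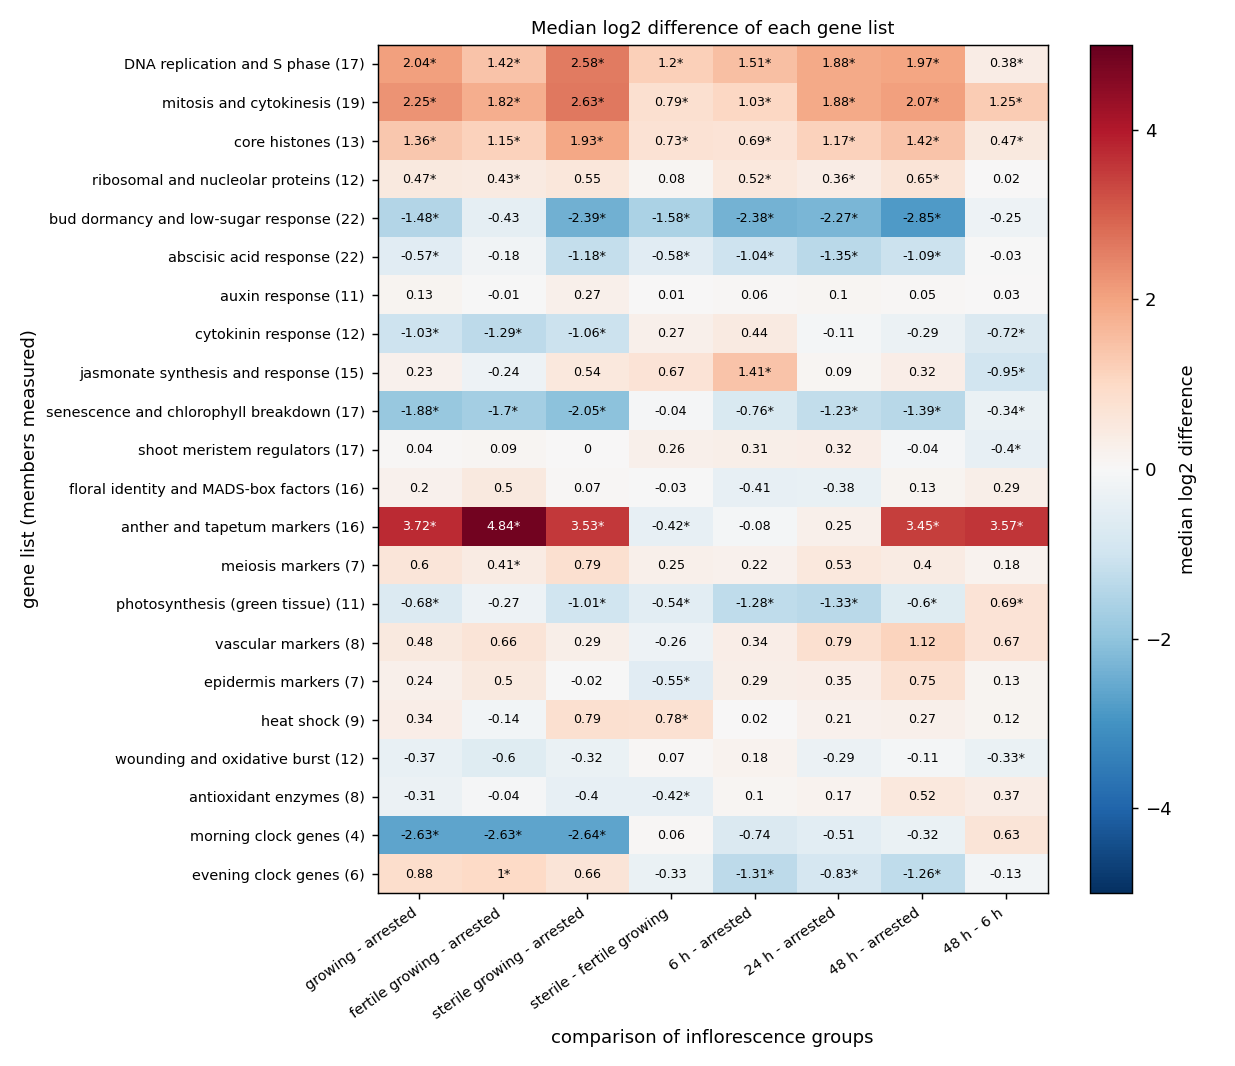
Median log2 difference of the 22 gene lists in the 8 comparisons of inflorescences. Red is higher and blue lower in the first group of the comparison. An asterisk marks an adjusted p under 0.05 by camera with the preset correlation, and none of these held with an estimated correlation.

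Division genes and tapetum markers were higher than arrested in both fertile and sterile growing inflorescences, and more dormancy genes fell in sterile ones. In fertile inflorescences the lipid transfer gene LTP12 (8.41 ± 0.43), the pollen coat oleosin GRP19 (8.22 ± 0.5) and A9 (AT5G07230, 8.41 ± 0.33) of the tapetum were among the genes that rose most, and 14 of 16 tapetum markers rose (15 adjusted over the list alone). Mitosis genes rose in 15 of 19 cases and replication genes in 11 of 17 (17 and 14 adjusted over the list alone). Dormancy genes fell in only 3 of 22 cases, with 19 not called (3 fell adjusted over the list alone), and the list's shift was not called (-0.43, adjusted p = 0.18). In sterile inflorescences 10 of 16 tapetum markers rose (10 adjusted over the list alone), along with the phosphatase PAP6 (5.49 ± 0.51) and the beta-amylase BAM5 (5.3 ± 0.35). Here 9 of 22 dormancy genes fell (9 adjusted over the list alone), as did the drought-inducible linker histone HIS1-3 (-6.69 ± 0.37) and the pollen arabinogalactan gene AGP6 (-6.88 ± 0.68). The dormancy median was -2.39 (camera adjusted p = 5.3e-07, adjusted p = 0.6 with an estimated correlation). Its size rested in large part on the g-coded arrested array. The list mean was 8.63 in the r-coded and 11.11 in the g-coded arrested array, against 7.46 in the sterile array. In total 2822 loci were called for fertile (1276 higher, 1546 lower, and 4383 without arrested replicate 1) and 5595 for sterile inflorescences (3314 higher, 2281 lower). Each growing group was a single array, and the number of arrays limits the precision.

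Among the genes that fell most in sterile against fertile inflorescences were genes of the tapetum and the pollen coat. LTP12 (-8.03 ± 0.49, adjusted p = 0.00097), GRP19 (-7.73 ± 0.58), the tapetum methyltransferase TSM1 (-6.94 ± 0.35) and A7 (-6.03 ± 0.41) fell, as did the pollen coat lipases EXL4 (-6.15 ± 0.69) and EXL6 (-5.9 ± 0.87). These included 3 of 16 tapetum markers, and 13 were not called (5 fell adjusted over the list alone), and CYP704B1 was among those not called (0.39, a gene chosen after the values were seen). Also lower were RAB18 of the abscisic acid list (-4.68 ± 0.63), the dormancy genes DRM2 (AT2G33830, -5.57 ± 0.88) and HB40 (-2.34 ± 0.38), and the auxin conjugating enzyme GH3.5 (-2.86 ± 0.35). Higher in sterile were BAM5 (4.08 ± 0.41, adjusted p = 0.0071), DDB1B of the DNA damage complex (3.89 ± 0.31), the cytochrome CYP82C2 (3.48 ± 0.31), the heat stress factor HSFA2 (3.1 ± 0.32), and CYP83B1 of indole glucosinolate synthesis (2.73 ± 0.44). In total 142 loci were called, 33 higher and 109 lower (23.2% higher). With the r or g code as a block 858 were called and 54.3% of them were higher. Both growing arrays were r-coded, so the block changed only the estimate of spread, by taking the arrested pair out of it. The count fell when either 24 h array was left out, so neither the count nor the balance of directions was stable. HB40 and CYP83B1 were not called after quantile normalization, and DRM2 not after median centring. By camera the lists of dormancy (-1.58, adjusted p = 2.2e-09, adjusted p = 0.58 with an estimated correlation), tapetum (-0.42, adjusted p = 4.8e-07, adjusted p = 0.55 with an estimated correlation) and abscisic acid response (-0.58, adjusted p = 5.3e-07, adjusted p = 0.55 with an estimated correlation) were lower. Replication genes were higher (1.2, adjusted p = 2.3e-06, adjusted p = 0.57 with an estimated correlation), with 15 of 17 passing when adjusted over the list alone although limma called 0 over all genes (15 at an unadjusted p under 0.05). With 1 array on each side, the test rested on the spread of the other groups, and over all genes the median difference was 0.25.

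Within 6 h of fruit removal most replication genes had risen and part of the dormancy genes had fallen. DRM2 (-6.12 ± 0.62, adjusted p = 0.0023), DRM1 (AT1G28330, -4.32 ± 0.64), HB21 (-3.04 ± 0.24) and HB40 (-2.61 ± 0.27) were among 10 of 22 dormancy genes that fell. Another 12 were not called (15 fell adjusted over the list alone). DRM2 and DRM1 were also high in the fertile growing array (12.85 and 12.36). They read 10.94 and 10.72 in the r-coded and 12.93 and 12.45 in the g-coded arrested array. HB21 read 8.05 in the fertile growing array, against 9.87 and 10.43 in the arrested arrays. The size of the dormancy shift at 6 h, 24 h and 48 h rested in large part on the g-coded arrested array: the list mean was 8.63 in the r-coded and 11.11 in the g-coded arrested array, against 7.47 and 7.65 at 6 h. PCNA1 (2.81 ± 0.22) and MCM2 (2.42 ± 0.27) were among 14 of 17 replication genes that rose (15 adjusted over the list alone), and 10 of 19 mitosis genes rose (11 adjusted over the list alone), CYCB1;1 by 1.41. Jasmonate genes rose in 9 of 15 cases, with 6 not called (11 rose adjusted over the list alone): the repressor JAZ5 (4.06 ± 0.41), the synthesis genes AOS (1.94 ± 0.21) and OPR3 (1.7 ± 0.24), and JAZ10 (2.94 ± 0.51). Of the named genes BAM5 rose most (6.12 ± 0.29), followed by TBL26 (4.6), the mannan synthases CSLA01 (4.35) and CSLA10 (3.75), the jasmonate methyltransferase JMT (4.09) and the flavonoid gene CHIL (3.72). Photosynthesis genes fell in 10 of 11 cases (11 adjusted over the list alone), among them PSBO1 (-1.6), GAPA (-1.41) and the Rubisco activase RCA (-1.27). The metal-binding gene HIPP22 (-5.61 ± 0.2) and the bHLH gene UPB1 (-4.71 ± 0.43) fell as well. Tapetum markers stayed near the arrested values, with a list median of -0.08 and 1 of 16 called, DRL1 at -1.27 (1 fell adjusted over the list alone).

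At 6 h 4622 loci were called against arrested, 1845 higher and 2777 lower, so that 39.9% were higher, but 54.3% were higher after quantile normalization. Without 6 h replicate 1 the count was 956. The split between rises and falls depended on the scaling of the arrays, and the count on the pair of arrays at 6 h. By camera, replication (1.51, adjusted p = 5.6e-12, adjusted p = 0.55 with an estimated correlation), jasmonate (1.41, adjusted p = 2.5e-07, adjusted p = 0.55 with an estimated correlation) and dormancy genes (-2.38, adjusted p = 4.1e-06, adjusted p = 0.66 with an estimated correlation) had shifted. Photosynthesis (-1.28, adjusted p = 6.7e-06, adjusted p = 0.57 with an estimated correlation) and abscisic acid response (-1.04, adjusted p = 0.0018, adjusted p = 0.55 with an estimated correlation) were lower.

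At 24 h most division genes were higher than arrested, and 24 h was not tested against 6 h. Mitosis genes rose in 17 of 19 cases and replication genes in 15 of 17 (18 and 16 adjusted over the list alone), with PCNA1 at 3.31 and CYCB1;1 at 2.28. Dormancy genes fell in 11 of 22 cases (11 adjusted over the list alone), abscisic acid genes in 9 of 22 (16 adjusted over the list alone) and photosynthesis genes in 9 of 11 (11 adjusted over the list alone), among them COR47 (-3.48 ± 0.39) and LHCA1 (-2.02 ± 0.32). BAM5 (6.51 ± 0.29), CSLA01 (4.84 ± 0.37) and the lectin gene JAL23 (4.82 ± 0.39) rose, and HIPP22 (-5.23 ± 0.2) and the carotenoid cleavage gene NCED4 (-4.16 ± 0.22) fell. The jasmonate list had 5 of 15 genes higher (5 adjusted over the list alone), AOS by 1.28 and JAZ5 by 2.41, while its shift was not called (0.09, adjusted p = 0.32). In total 4658 loci were called, 2220 higher and 2438 lower, and 1786 without 24 h replicate 2. Camera called mitosis (1.88, adjusted p = 2.3e-10, adjusted p = 0.55 with an estimated correlation) and dormancy (-2.27, adjusted p = 3e-07, adjusted p = 0.6 with an estimated correlation).

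By 48 h tapetum markers were higher than arrested, and division genes stood near the values of growing inflorescences. Whole inflorescences were sampled, so a switch within buds and other floral stages cannot be told apart here. Of 16 tapetum markers 14 rose and 2 were not called (14 adjusted over the list alone): the bHLH regulator AMS (4.19 ± 0.26), the fatty acyl reductase MS2 (5.4 ± 0.34), CYP704B1 (6.52 ± 0.42) and CYP703A2 (4.38 ± 0.29). Mitosis genes rose in 18 of 19 cases (19 adjusted over the list alone), with CYCB1;1 at 2.85 ± 0.27, and replication genes in 14 of 17 (15 adjusted over the list alone). Dormancy genes fell in 11 of 22 cases, with 11 not called (14 fell adjusted over the list alone), HB53 by 2.91, HB21 by 3.36 and HB40 by 3.16 log2 units. Senescence genes fell in 8 of 17 cases, with 9 not called (10 fell adjusted over the list alone), among them SAG12 (-4.05 ± 0.3), SAG21 (-3.22 ± 0.24) and NAP (-4.18 ± 0.34). Of 8 vascular markers 5 rose and 1 fell (6 and 1 adjusted over the list alone), the xylem genes IRX5 (1.87) and XCP2 (1.68) against the phloem transporter SUC2 (-2.65), and XCP2 was not called with the code as a block. The stem cell gene WUS rose by 1.85 and the floral regulator LFY stood at -1.45. In total 5596 loci were called, 2658 higher and 2938 lower, and 3142 without 48 h replicate 2. Camera called tapetum (3.45, adjusted p = 5.6e-12, adjusted p = 0.3 with an estimated correlation), mitosis (2.07, adjusted p = 5.6e-12, adjusted p = 0.55 with an estimated correlation), dormancy (-2.85, adjusted p = 1.2e-06, adjusted p = 0.62 with an estimated correlation) and senescence (-1.39, adjusted p = 6.4e-05, adjusted p = 0.58 with an estimated correlation).

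**Figure D2:**
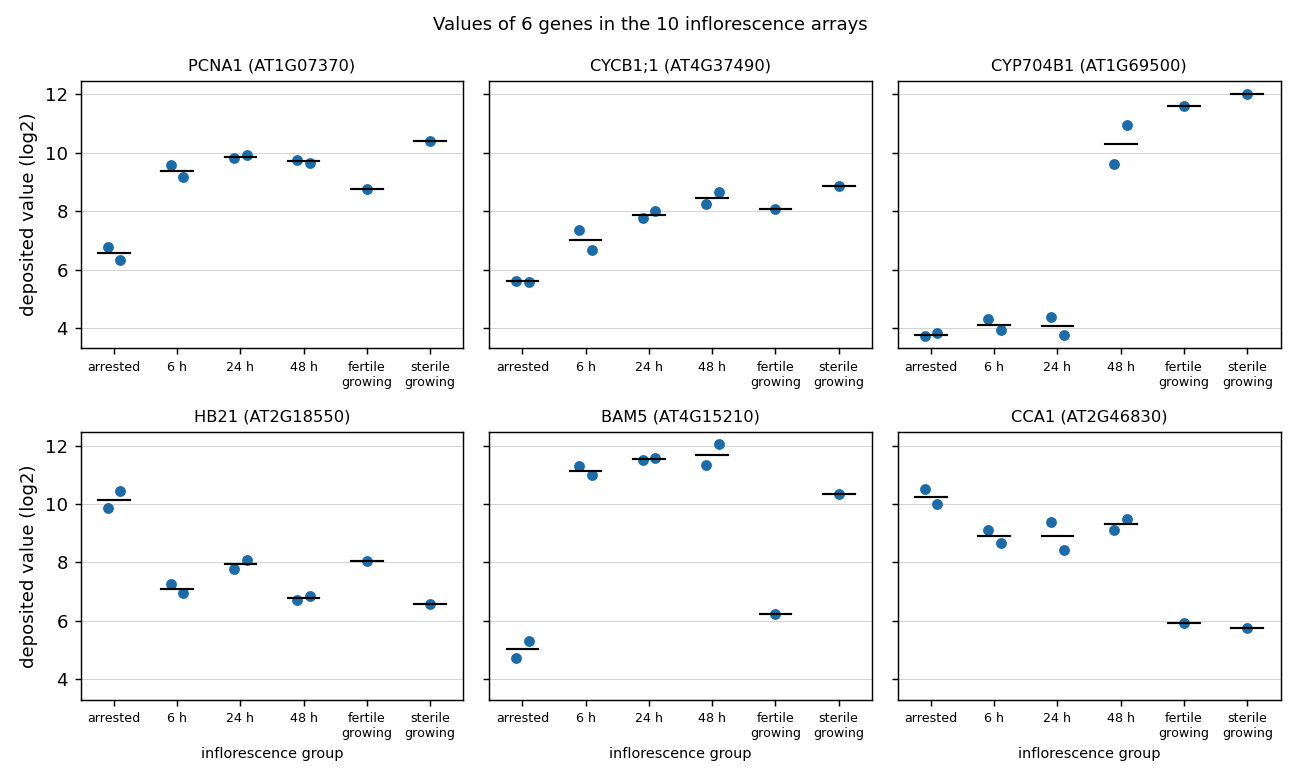
Deposited log2 values of PCNA1, CYCB1;1, CYP704B1, HB21, BAM5 and CCA1 in the 10 inflorescence arrays. Dots are arrays and bars are group means, with 1 array each for fertile and sterile growing inflorescences.

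Between 6 h and 48 h the rise of tapetum genes dominated. Of 16 markers 13 rose and 3 were not called (14 rose adjusted over the list alone), among them DRL1 (4.02 ± 0.22), AMS (4.44 ± 0.26) and MS2 (5.45 ± 0.34), and with them the anther genes A9 (6.93 ± 0.27), ATA27 (5.87) and ATA20 (5.85). In the mitosis list CYCB1;1 (1.44), AUR2 (1.51) and CYCB2;2 (1.53) rose and 16 of 19 were not called (18 rose adjusted over the list alone). The copper-zinc superoxide dismutases CSD2 (2.72) and CSD1 (2.19) rose too. Among fallers were the phytosulfokine precursor PSK2 (-2.53 ± 0.19), the peroxidase PRX52 (-2.39), the sucrose transporter SUC1 (-2.18) and the senescence genes SAG21 (-1.46) and SAG12 (-1.55). Over all loci 633 were called, 437 higher and 196 lower, with 1757 called with the code as a block. All 6 h and 48 h arrays were g-coded, so the block changed only the estimate of spread. The count fell strongly when a 6 h array was left out. The tapetum list led by camera (3.57, adjusted p = 7.9e-21, adjusted p = 0.25 with an estimated correlation), and jasmonate genes were lower at 48 h (-0.95, adjusted p = 7.3e-07, adjusted p = 0.55 with an estimated correlation). In that list limma called 0 of 15 genes (9 at an unadjusted p under 0.05, 8 adjusted over the list alone).

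After fruit removal most genes that were also called in growing minus arrested moved towards the growing state. The dormancy genes DRM2 and DRM1 were high in the fertile growing array, so their falls led away from that array. No arrays of untreated or wounded plants taken at the same hours are in the series. Wounding and harvest hour therefore go together with fruit removal. Adjusted over the list alone, 5 of 6 evening clock genes fell at 48 h, and of 4 morning clock genes 1 rose. On disjoint arrays, growing minus the r-coded arrested array correlated with fruit removal minus the g-coded arrested array at 0.419 for 6 h, 0.562 for 24 h and 0.698 for 48 h. Of the genes higher in growing inflorescences 1933 were also higher at 48 h, against 370.8 for independent lists, and 1863 of the lower ones were also lower, against 350.1. Opposite calls numbered 5 and 7. At 6 h the shared calls were 1055 higher and 1431 lower, against 257.4 and 331. With all arrays the correlation at 48 h was 0.861, whereas simulated groups without any effect gave 0.502 because the arrested arrays were shared, and the covariance was 0.748 against a simulated 0.039. At 6 h the correlation was 0.617 against a simulated 0.5, and the covariance 0.437 against 0.039. The simulated groups held noise alone, so the shared arrays gave all of their correlation, and it is no measure of the shared part in the data. On disjoint arrays the 6 h correlation was 0.419. Part of the excess of shared calls may come from these shared controls. Simulated groups without any effect shared 0 calls at 48 h, against 3808 observed in either direction. Such groups do not show how real effects share calls.

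The arrested meristem also carried less of the division program and more of the dormancy and abscisic acid program than the other 3 meristems. Mitosis genes had medians of 1.29, 1.18 and 1.28 in fertile growing, sterile growing and fruit removal meristems minus arrested, and replication genes 1.05, 0.89 and 0.9, each at percentile 100 of random lists. The telomerase gene TERT read 4.86 in the arrested meristem against 8.22, 8.56 and 8.23, and ATN read 4.83 against 8.8, 8.94 and 9.34. Abscisic acid genes had medians of -0.92, -1.39 and -1.13 and dormancy genes -0.86, -1.26 and -1.24, each at percentile 0. HB-7 read 10.27 in the arrested meristem against 6.43, 6.52 and 7.2, the dehydrin LTI30 12.07 against 10.13, 6.41 and 7.56, and DRM2 11.72 against 9.59, 8.04 and 6.11. HIPP22, which fell in inflorescences after fruit removal, read 11.05 against 6.04, 6.57 and 7.84. Cytokinin response genes had medians of 0.27, 0.4 and 0.6, at percentiles 93.9, 94.3 and 99.8. The medians of shoot meristem regulators were 0.06, 0.05 and 0.12, at percentiles 41.6, 39.7 and 55.3. Those of senescence genes were -0.09 (within the central range of random lists), -0.24 and -0.23 (percentiles 1.5 and 1.9), and those of photosynthesis genes -0.57, -0.17 and -0.42, at percentiles 0.1, 14.2 and 1.9. Morning clock genes had medians of -1.1, -1.21 and -0.59 (percentiles 0.1, 0.1 and 2.1) and evening clock genes -0.63, -0.68 and -0.94 (percentiles 0.2, 0.3 and 0). At least 4-fold apart from arrested were 263 loci in fertile growing, 335 in sterile growing and 259 in fruit removal meristems, and 32 loci differed so between sterile and fertile. With 1 array per group no test was made, and the spread between meristem arrays of a group is not known. Genes of the random lists were drawn independently, whereas genes of a list can move together, so the percentiles are not p-values. All 3 comparisons with arrested share the 1 arrested array.

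**Figure D3:**
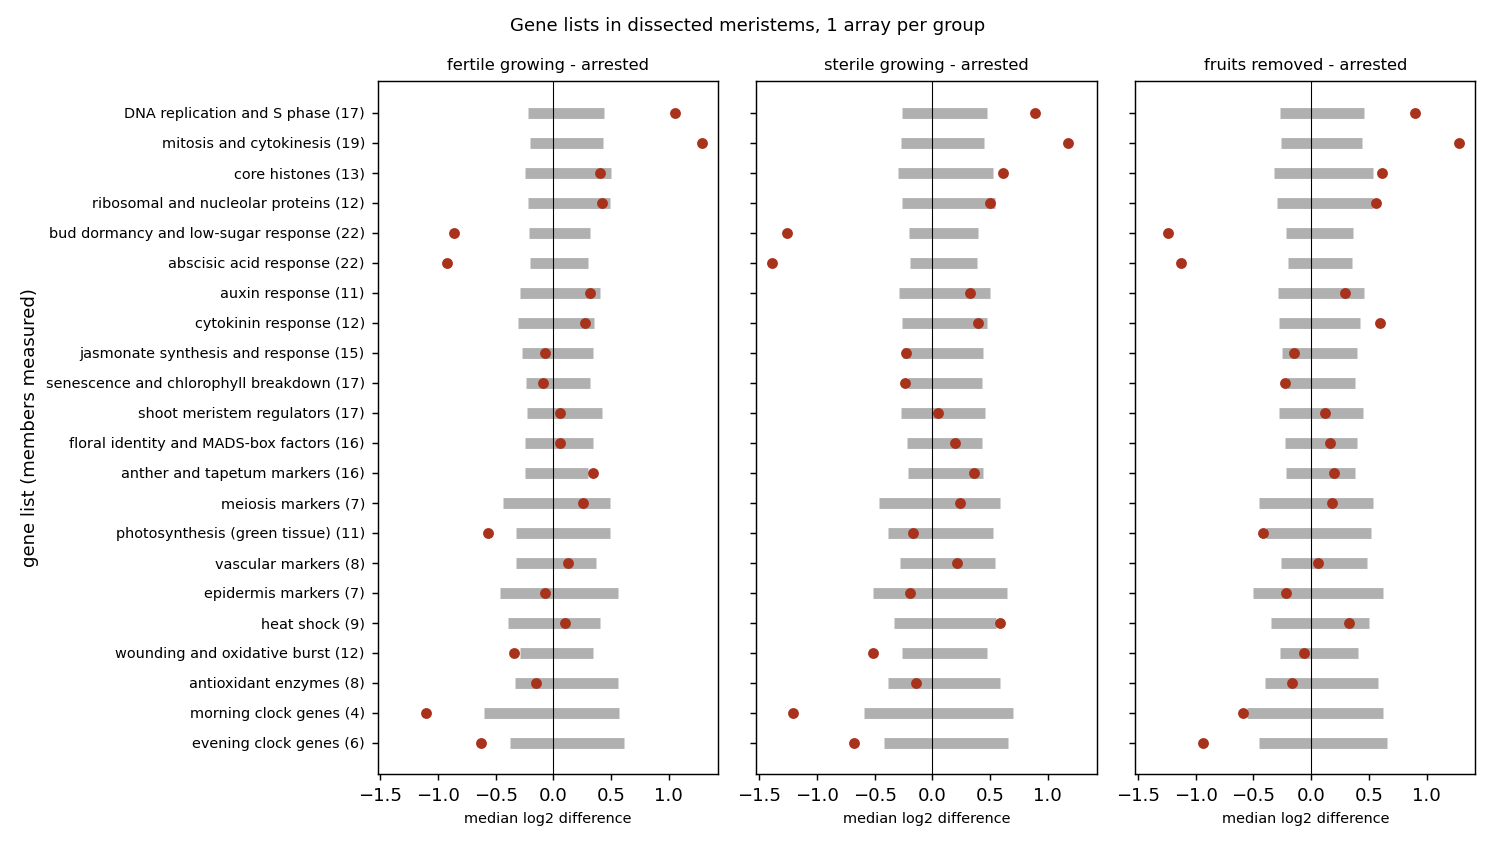
Median log2 difference of the 22 gene lists between meristems and the arrested meristem (dots). Grey bars span the central 95% of medians of random lists matched in size and expression.

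In the 3 comparisons with arrested material, most called genes had the same direction in both tissues. Of genes called in inflorescences 48 h after fruit removal and differing in meristems, 4228 of 5561 (76%) had the same sign in meristems. The share was 59% among all remaining genes. These included loci with a meristem difference of 0 (133 of 21195), which counted as unlike and lowered that share. For sterile growing, 4194 of 5566 called genes had the same sign (75.4%, against 60% of the remaining genes). For fertile growing it was 1945 of 2804 (69.4% against 57.5%). For sterile minus fertile it was 69 of 141 (48.9% against 55%, with 304 loci at a difference of 0). There the called share exceeded the remaining one with quantile normalization (57.9% against 54.2%) and without the genes below the median (55.4% against 52.4%). Correlations across genes were 0.395, 0.366, 0.253 and 0.101 in the same order. DDB1B was higher in sterile than in fertile material of both tissues, at 8.74 in the sterile inflorescence array and at 8.34 in the sterile meristem against 5.21 in the fertile one.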

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

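The tests within r-coded or g-coded arrays, the test of noise in the arrested meristem and the test of its share of meristem cells were chosen only after the result was seen. The late pollen, dawn and evening lists were also chosen after the main results, with their bounds written before those lists were looked at. For list medians, an outcome was held to be met only where the value lay past its written bound. The interval printed beside it had also to lie past the bound of the opposing outcome. This rule was added after the values were seen and left 4 tests undecided. Its intervals ran between ordered members of a list. For the morning clock, dawn, evening and copper lists they ran from the lowest to the highest member. There they show the spread of members and carry no level of confidence. By value alone the late pollen test would have spoken for its explanation, and the tests of harvest hour, meristem share and copper against theirs.

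Tapetum markers were low in arrested inflorescences and at 6 h, and high at 48 h and in growing inflorescences. A difference between r-coded and g-coded arrays as the cause would put their median at 48 h minus the g-coded arrested array under 1 (log2). The median was 3.26 (1.94 to 4.15), which argues against it for this difference. All 6 h and 48 h arrays were g-coded and had already shown the rise. The outcome could thus be foreseen and is no separate support. Arrested inflorescences could instead hold buds of other floral stages. Late pollen markers outside the list would then differ by over 1. Their median in growing minus arrested was -1.86 (-4.37 to -0.17), with higher late pollen values in arrested inflorescences. The growing groups included the male sterile array, so part of this value could come from the genotype. The median was -1.44 for the fertile and -2.11 for the sterile array minus arrested. By value the written bound was met, and of 12 markers 8 fell and 4 were not called, which goes with other floral stages. The interval, used under the rule added later, came within 0.5 of 0. A switch of the tapetum program within buds of like stage was therefore not excluded, and the 2 cannot be told apart.

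Morning clock genes were lower in both growing groups than in arrested inflorescences. An effect of the r or g code would put their median within the r-coded arrays above -1, and it was -2.36 (-4.66 to -1.59), which argues against it. The test reused arrays that had shown the pattern, so it is no separate support. Harvest at another hour of the day might be the cause. Dawn-phased genes outside the list had a median of -2.33 (-2.99 to -0.79), and evening-phased genes had -0.27 (-1.04 to 1.2), so harvest hour and a change of the clock itself cannot be told apart. In meristems minus arrested, morning clock genes (-1.1, -1.21 and -0.59) and evening clock genes (-0.63, -0.68 and -0.94) both had negative medians, whereas 3 of 6 evening genes rose in growing inflorescences. Of those 3 risers, GRP7 and TOC1 were not called with the r or g code as a block.

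The arrested meristem array stood apart from the other 3 meristem arrays, at correlations of 0.923, 0.914 and 0.904 against 0.974 to 0.975 among the others. Random noise in that array as the whole cause would leave called and uncalled inflorescence genes with like shares of the same sign. Called genes exceeded the remaining ones by 17 points, which argues against it. Loci with a meristem difference of 0 (133 of 21195) were among the remaining ones and counted as unlike, which widened the gap. A lower share of meristem cells in that dissection could also play a part. The highest of the 3 medians of shoot meristem regulators was 0.12 (-0.15 to 0.7), so a lower share of meristem cells and arrest itself cannot be told apart. Photosynthesis genes, a marker of green tissue, had medians of -0.57, -0.17 and -0.42 (percentiles 0.1, 14.2 and 1.9) in the other meristems minus arrested.

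Between 6 h and 48 h after fruit removal camera with the preset correlation called 6 lists that held a gene called by limma. They were mitosis (median 1.25), core histone (0.47), cytokinin response (-0.72), senescence (-0.34), tapetum (3.57) and photosynthesis genes (0.69). The jasmonate list, without such a gene, was called as well and is given above. Of these none was called by camera with an estimated correlation (lowest adjusted p = 0.25, tapetum). COR15A was higher in growing inflorescences by 3.39 and lower than arrested in the other meristems (7.27 arrested, 6.03 to 6.18 in the others), the difference between tissues was not tested, and the inflorescence value was 1.75 and not called with the r or g code as a block. CLV1 stood at -1.12 in growing minus arrested inflorescences and was higher than arrested in the other meristems (8.55 arrested, 10.33 to 10.91 in the others), and the difference between tissues was not tested.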

How the results depend on the processing

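No test below was chosen only after the result was seen, and all alternatives were chosen before the data were examined. The code differed within a group only in the arrested pair. The block fit therefore took that pair out of the estimate of spread, as leaving out 1 arrested array did, and these are not separate checks. The 142 calls of sterile minus fertile became 858 with the r or g code as a block (54.3% higher, against 23.2%), 44 without the genes whose mean lay below the median and 302 at an adjusted p under 0.1. They ranged from 42 (without either 24 h array) to 858 (without either arrested array) as single arrays were left out, with 71 without either 6 h array. The 633 calls of 48 h minus 6 h became 1757, 414 and 1481 in the same order and ranged from 77 (without 6 h replicate 2) to 1757 (without either arrested array), with 102 without 6 h replicate 1, 270 without either 24 h array, and 278 and 185 without 48 h replicate 1 or 2. Against arrested, single arrays moved the calls for fertile from 1921 (without either 6 h array) to 4383 (without arrested replicate 1), for 6 h from 956 (without 6 h replicate 1, 1125 without replicate 2) to 5787 (without arrested replicate 1), for 24 h from 1786 (without 24 h replicate 2, 2132 without replicate 1) to 5720 (without arrested replicate 1) and for 48 h from 3142 (without 48 h replicate 2, 3436 without replicate 1) to 6555 (without arrested replicate 1). Of the 176 list tests 80 passed by camera, and 0 with an estimated correlation, where 14 had an unadjusted p under 0.05. With fry, which tests a list against no change and not against other genes, 46 passed. In meristems the same filter gave 128, 186, 157 and 5 loci at 4-fold, in place of 263, 335, 259 and 32. Correlations on disjoint arrays with that filter, quantile normalization and ranks were 0.619, 0.55 and 0.586 at 24 h and 0.717, 0.702 and 0.64 at 48 h. Between tissues they were 0.338, 0.243 and 0.293 for fertile, 0.453, 0.369 and 0.372 for sterile, 0.512, 0.389 and 0.41 for fruit removal, and 0.133, 0.112 and 0.112 for sterile minus fertile. No direction of a named gene was reversed, but genes named for the largest differences had been picked for arrays that did not overlap. Neither leaving out an array nor the block could reverse those, so this says nothing of their stability. Of 261 gene values, 4 lost their call with quantile normalization and 5 with median centring (JAL23, CYP83B1 and HB40 in sterile minus fertile in both), 7 with the code as a block (COR15A, GRP7, JAZ12, PSBO1, TOC1 and ZAT10 in growing minus arrested, XCP2 at 48 h), 31 and 29 without 6 h replicate 1 or 2, 27 without either 24 h array, 15 and 20 without 48 h replicate 1 or 2, and 1 and 6 without arrested replicate 1 or 2. No paired analysis was possible because replicate numbers were given in the order of accession, and no pairing of samples is stated in the labels.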

Other observations

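All lists below were chosen only after the main results had been seen, so their p-values describe these arrays and are no separate support. For the copper tests the bounds were written before those lists were looked at.

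Flavonoid synthesis genes rose after fruit removal, 11 of 11 at 6 h (median 2.77, camera adjusted p = 6.4e-09, adjusted p = 0.5 with an estimated correlation) and 11 of 11 at 48 h (2.42), with 11 rising adjusted over the list alone at both. The regulator PAP1 (3.35), the hydroxylase TT7 (3.3) and the flavonol synthase FLS1 (3.11) were among them at 6 h. In growing minus arrested 5 of 11 rose and 6 were not called (8 rose and 1 fell adjusted over the list alone), with PAP1 at -0.98 and not called.

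Aliphatic glucosinolate genes fell in growing inflorescences against arrested ones, 6 of 11 with 5 not called and 8 adjusted over the list alone (median -1.87, camera adjusted p = 0.00011, adjusted p = 0.5 with an estimated correlation), among them BCAT4 (-5.57), MAM3 (-4.2) and the regulator MYB28 (-2.24). At 48 h after fruit removal limma called 0 of 11 (0 at an unadjusted p under 0.05), and the median was -0.38. Indolic glucosinolate genes were higher in sterile than in fertile inflorescences, 3 of 8 with 5 not called and 5 adjusted over the list alone (1.97, camera adjusted p = 0.0052, adjusted p = 0.5 with an estimated correlation), SOT16 by 2.21, CYP83B1 by 2.73 and MYB34 by 1.85. CYP83B1 had been named in this comparison before the list was chosen and was kept in it. It was not called after quantile normalization or median centring.

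Late pollen genes fell in 8 of 12 cases in growing minus arrested, with 4 not called and 8 falling adjusted over the list alone. BCP1 (-5.64), AGP11 (-5.39) and STP11 (-4.37) were among them. The growing groups included the male sterile array, and the median was -1.44 for fertile and -2.11 for sterile minus arrested. After fruit removal 7 of 12 fell, 1 rose and 4 were not called at each of 6 h, 24 h and 48 h, with medians of -1.31, -1.07 and -1.49 (7, 7 and 9 fell adjusted over the list alone). Of the dawn-phased genes 6 of 8 fell and 2 were not called, with COL1 at -2.99 and LNK2 at -2.68, and of the evening-phased genes 1 of 6 fell, and adjusted over the list alone these counts were the same.

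Copper supply could differ between arrested and growing inflorescences, since FSD1 (-5.94) fell while CSD2 (3.26) and CSD1 (2) rose, a pattern seen in plants when copper becomes available. Other genes induced in copper deficiency would then have a median under -0.5 and other copper proteins a median over 0.5. The medians were -0.54 (members from -3.15 to 0.99) and -0.36 (members from -1.16 to 1.89), with CCH at -3.15 and ARPN at 1.89. Under the rule added later, copper and other causes cannot be told apart. Of the copper deficiency genes 1 rose, 2 fell and 1 was not called, and of the copper proteins 2 rose, 1 fell and 4 were not called (1 and 2, and 2 and 2, rose and fell adjusted over the list alone).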
